A study of Daphnia magna with 8 samples.

How the data were processed

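RNA abundance was measured in whole Daphnia magna, a planktonic freshwater crustacean, of the clone BL2.2. Per the labels, animals younger than 24 h were placed in 50 mL of medium and fed the green alga Scenedesmus obliquus at 1.5 mg carbon per litre, reduced to 1 mg per litre after 6 days, with a full change of medium after 14 days. Exposed animals received particles of polyvinyl chloride (PVC), or PVC with DINP (di-isononyl phthalate, a plasticizer), at a ratio of 1 particle to 10 algal cells, and control animals received no particles. Animals were harvested while carrying their 7th brood, and whether the brood was removed is not given in the sources used here. The labels name 2 biological replicates per condition, which makes 6 RNA extracts; the number of animals per extract is not given in the sources used here, so the spread between extracts is taken as it stands.

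The extracts were labelled with Cy3 and Cy5 and hybridised in pairs to 8 dual-colour Agilent arrays, all on 1 slide read in 1 scan. Every array paired 2 extracts of the same replicate number. PVC+DINP and control shared 4 arrays, with the dyes swapped within each replicate; PVC and control shared 2 arrays, and PVC+DINP and PVC shared 2 arrays, with the dyes in opposite orientation in the 2 replicates. The 16 channel readings comprised 6 of control, 4 of PVC and 6 of PVC+DINP.

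Spot intensity was extracted with Agilent Feature Extraction 11.5.1.1, per the file headers, which record a median intensity and a median background for each spot and dye, processed intensities after background subtraction and dye normalization, and flags for spots that were non-uniform, saturated or well above background. The deposited files also carry the log10 ratio of Cy5 over Cy3 processed intensity, which, on spots where it was not 0, equalled the ratio of the processed intensities within 1.3e-06 on the log2 scale on every array. A deposited value table gives 1 log2 ratio per spot and array. The submitters' processing notes name limma without a version, and the normalization behind this table is not given in the sources used here. Set against the scanner's ratios on spots with a median signal above 3000 in both dyes, its columns had slopes between 0.986 and 0.998 and correlations between 0.995 and 0.999, which gives a log2 scale with Cy5 over Cy3; over all spots the correlations lay between 0.738 and 0.828. The medians of its columns lay between 0.000107 and 0.00734. The value table served as an alternative.

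Median intensities were corrected against the local background by normexp with an offset of 50, and log2 ratios were normalized within each array by loess, with control spots and non-uniform spots at weight 0 (limma 3.58.1 in R 4.3.3). The analysis had been planned on mean intensities; the files used here give medians, and these took their place. For each probe, the 8 ratios were resolved by least squares into extract values within each replicate number and 1 dye effect, which left 3 technical residual degrees of freedom, so that technical arrays did not count as replicates. The 6 extract values were then fitted in limma with condition and replicate number as terms, leaving 2 residual degrees of freedom, to which the empirical Bayes step added 2.97. All 3 comparisons came from this fit, with Benjamini-Hochberg adjustment and a threshold of 0.05. The replicate number was a term because ratios exist only within it. In separate-channel values, deviations of same-numbered extracts from their condition means correlated across probes at -0.263 for control with PVC, 0.0953 for control with PVC+DINP and 0.158 for PVC with PVC+DINP.

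Of 61657 probes, 25274 (41.0%) were well above background in every reading of at least 1 condition and were tested; they represent 22827 transcripts, and 22457 of them were well above background in all 16 readings. Between 39.3% and 46.8% of probes per array were well above background in Cy3, and between 41.6% and 45.4% in Cy5. No spot was saturated. The 770 spike-in spots per array had median intensities at most 5.75 above those of the 308 negative control spots in either dye, so no external standard was used, and ratios describe change relative to the bulk of probes on the array. The number of extracts limits the precision: the median standard error of a log2 ratio was 0.12, a 95% half-width of 0.32. Replicate agreement was described by the number of tested probes at least 2-fold apart in the same direction in both replicate numbers, beside the number apart in opposite directions, and by the correlation of the log2 ratios of both replicate numbers across probes, which are not independent replicates. Chance values came from 50 simulated data sets on the same array scheme with no effect of condition. Noise between extracts was drawn independently for each probe there, so a difference of 1 extract that moves many probes together is not represented.

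The array files give transcript IDs without gene names. None of the 56910 IDs matched the 28335 genes of the RefSeq table, so the 24 gene lists fixed before the data were examined had 0 members and no gene list was tested. Under the rule fixed at that stage for unnamed features, at most 2 higher and 2 lower transcripts are given per comparison: those past the threshold with the largest change or, as none passed, those with the smallest unadjusted p among transcripts changed in the same direction in both replicates with a mean log2 ratio of at least 1 in size. A transcript with several probes was represented by its brightest.

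The procedure was tested on simulated data for PVC+DINP over control on 25274 probes, with 200 probes changed by known folds, 50 at each size. With spreads drawn from the distribution limma had fitted, 30% of 2-fold, 96% of 4-fold, 98% of 8-fold and 100% of 16-fold changes were called. With each probe's own moderated variance, 84% of 2-fold and 100% of larger changes were called. With the changed probes given the spreads of the probes that were higher in both replicates under PVC+DINP, 4% of 2-fold, 28% of 4-fold, 32% of 8-fold and 62% of 16-fold changes were called. Calls of unchanged probes numbered 12 with the fitted distribution, 21 with moderated variances and 0 with these wider spreads. With moderated variances the empirical Bayes step added 4.70 degrees of freedom, against 2.97 in the data, so those rates may be too high. Alternatives were no background correction, the processed intensities, Aquantile normalization, the value table, no filter on dim probes, a stricter filter, no dye effect, no replicate block, arrays as independent, an intensity trend, an adjusted p under 0.10 and the omission of each extract. Added after the data were examined were the slide row as a block, scale normalization, the omission of the array with the high Cy3 signal or of both arrays with control replicate 2 in Cy3 and a crossed numbering of the PVC extracts. Figures were drawn with matplotlib 3.10.9.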

Results

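Whole Daphnia magna fed algae alone, algae with PVC particles or algae with PVC particles containing the plasticizer DINP were compared on 8 dual-colour arrays, with 2 extracts per condition. The arrays measured 61657 probes, of which 25274, for 22827 transcripts, were bright enough to test. The dye-swapped arrays of PVC+DINP and control gave log2 ratios that correlated across probes at 0.536 in replicate 1 and 0.685 in replicate 2. After removal of the dye effect these values were 0.948 and 0.971. The dye effect was estimated on the same arrays, so part of this rise is built in and is no separate measure of agreement. The median technical standard deviation was 0.11 on the log2 scale. Transcripts carry only the array's IDs, so they are described as groups and by ID.

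The comparison of PVC+DINP with control asked how plasticized particles alter the transcriptome. A group of 527 probes, for 525 transcripts, was at least 2-fold higher in PVC+DINP animals in both replicates, against 45 probes that were at least 2-fold lower in both and 66 that were apart in opposite directions. The higher group had a median log2 ratio of 2.08, with a median of 1.60 in replicate 1 and 2.57 in replicate 2; 135 of its probes were at least 4-fold and 13 at least 8-fold higher in both replicates. Simulated data without an effect gave a mean of 18.5 probes higher in both replicates (9 to 31 over 50 data sets), 21.3 lower in both (12 to 28) and 38.5 in opposite directions (29 to 50). The simulated noise was independent between probes, so these ranges do not cover an extract in which many probes move together. Of the higher group, 510 probes were well above background in all 16 readings, and the group's median intensity of 9.35 on the log2 scale lay above the 8.14 of all tested probes. The log2 ratios of both replicates correlated at 0.51 (Spearman 0.22) across all tested probes. A set of 47 probes, 2 of them in the higher group, was well above background in all 6 PVC+DINP readings and in no control reading, against 12 with the reverse pattern. The Cy3 readings of control replicate 2 had brighter negative control spots (medians 64.5 and 54.5), so these counts are not on an equal footing.

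The higher transcripts with the smallest p were daphmag3mtv3l9876t1, at a log2 ratio of 1.22 ± 0.11 (SE, n = 2 extracts per condition, adjusted p = 0.191), and daphmag3mtv3l12521t2, at 1.78 ± 0.17 (adjusted p = 0.191). Replicates 1 and 2 gave 1.14 and 1.30 for daphmag3mtv3l9876t1, and 1.85 and 1.71 for daphmag3mtv3l12521t2. The lower ones were daphmag3mtv3l3598t2, at -1.03 ± 0.26 (adjusted p = 0.271), and daphmag3mtv3l12020t1, at -1.45 ± 0.39 (adjusted p = 0.311); without control replicate 2 they stood at -0.65 and -0.80. The 45 lower probes had a median log2 ratio of -2.30, and they were also low in PVC replicate 2, with a median of -3.71 against control replicate 2, but not in PVC replicate 1, with a median of 0.56 against control replicate 1. Within each replicate, the PVC and PVC+DINP ratios hold the same control extract.

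No probe passed the threshold in limma for PVC+DINP over control (lowest adjusted p 0.191). At an unadjusted p under 0.05 in limma, 2155 probes stood where 1263.7 were expected by chance, 1940 of them higher and 215 lower. This expected number has no range, as probes of 1 extract can move together. The count was 1459 without the dye effect and 3152 with slide row as a block, and 670 for PVC over control. The 2155 included all 527 probes of the higher group and 21 of the 45 in the lower group. Groups chosen on the same ratios gain no separate support from this, here or in the other comparisons. The median residual standard deviation of the higher group was 0.58 on the log2 scale, 4.90 times that of all tested probes. The number of calls depended on which extract was left out. Each such fit leaves a condition with 1 extract, whose spread is not measured and is taken from the other conditions. The log2 ratio of daphmag3mtv3l9876t1 was 1.27 without PVC+DINP replicate 1 and 1.15 without PVC+DINP replicate 2. The number of probes apart in the same direction in both replicates was 572 here and 973 with the scanner's processed intensities.

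**Figure D1:**
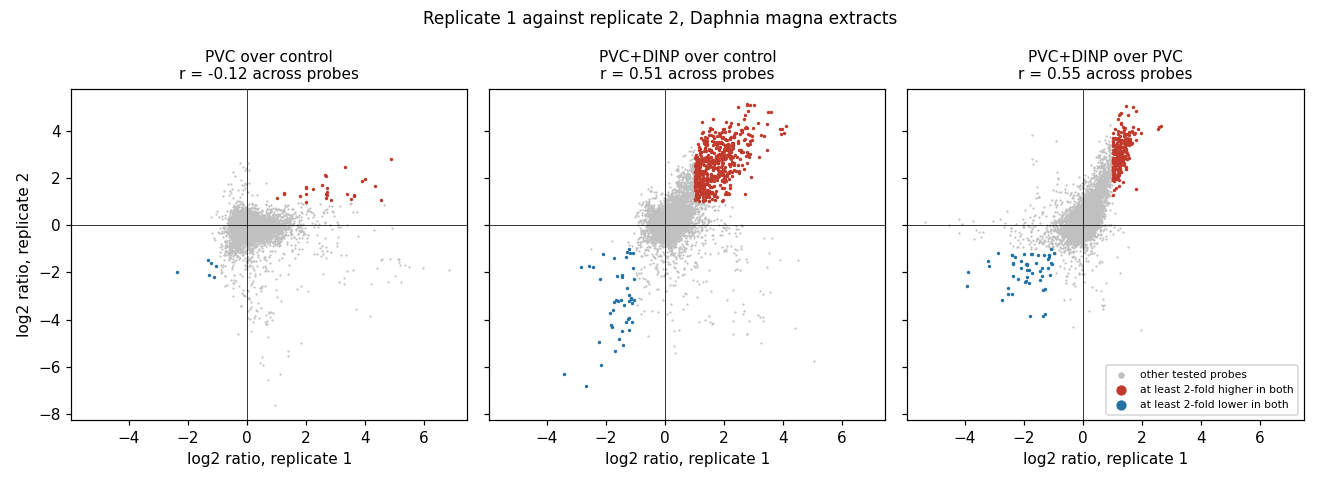
Log2 ratio in replicate 1 (x axis) against replicate 2 (y axis) for each of the 25274 tested probes, in 3 comparisons; coloured points are probes at least 2-fold higher or lower in both replicates. For PVC+DINP over control, 527 probes lie at the upper right and 45 at the lower left, whereas for PVC over control 28 and 6 do.

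The comparison of PVC with control asked what particles without the plasticizer do. Here 28 probes were at least 2-fold higher and 6 at least 2-fold lower in both replicates, and 56 were apart in opposite directions. Simulated data without an effect gave 9 to 33 higher, 9 to 32 lower and 31 to 55 opposite. The replicates differed in direction: in replicate 1, 445 probes were at least 2-fold higher and 12 lower in PVC animals, while in replicate 2, 64 were higher and 306 lower. The log2 ratios of both replicates correlated at -0.12 (Spearman -0.22) across probes, and at -0.38 without a dye effect in the model. All 56 opposite probes were higher in PVC in replicate 1, with a median log2 ratio of 2.63, and lower in replicate 2, with a median of -1.68.

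Of the lower transcripts, daphmag3mtv3l16618t1 was at -2.17 ± 0.13 (adjusted p = 0.418), with -2.37 in replicate 1 and -1.97 in replicate 2, and daphmag3mtv3l9809t1 was at -1.39 ± 0.12 (adjusted p = 1.00). The higher transcripts were daphmag3mtv3l4170t1, at 1.03 ± 0.20, and daphmag3mtv3l38215t1, at 2.12 ± 0.42, both with an adjusted p of 1.00; daphmag3mtv3l4170t1 stood at 0.62 without control replicate 1. In limma no probe passed the threshold for PVC over control (lowest adjusted p 0.418), and 670 probes had an unadjusted p under 0.05 where 1263.7 were expected by chance, among them 22 of the 28 higher and 6 of the 6 lower in both replicates. A total of 46 probes were well above background in all 4 PVC readings and in none of the 6 control readings. The reverse, all 6 control readings and no PVC reading, held for 1 probe. These counts are not on an equal footing, as the reverse asks for more readings. Those include the Cy3 readings of control replicate 2, where the negative control spots were brighter. The log2 ratio of daphmag3mtv3l38215t1 was 2.75 without control replicate 2 and 1.49 without control replicate 1. The 34 probes apart in the same direction in both replicates became 15 when brightness well above background was required in all 16 readings, 58 in the deposited value table and 124 with the processed intensities.

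The comparison of PVC+DINP with PVC asked what the plasticizer adds to the particle. Probes at least 2-fold higher in PVC+DINP animals in both replicates numbered 248, against 53 lower in both and 15 in opposite directions; simulated data gave 13 to 28 higher, 8 to 30 lower and 27 to 55 opposite. Both replicates correlated at 0.55 (Spearman 0.27) across probes, and at 0.10 without a dye effect in the model. Of the 248, 242 were also in the group of 527 higher than control. This overlap is 5.17 for independent lists. In the simulated data without effects it averaged 3.32 and reached at most 7, but the lists there averaged only 18.5 and 19.1 probes. The simulated counts are therefore no measure of chance for lists of 527 and 248. Part of the observed overlap may come from the PVC+DINP extracts that both comparisons share. The 248 probes had a median log2 ratio over PVC of 1.22 in replicate 1 and 2.99 in replicate 2. In the group of 527, PVC itself stood at a median of 0.70 above control in replicate 1, with 522 probes above 0 and 120 at least 2-fold, and at 0.0077 in replicate 2, with 271 above 0 and 2 at least 2-fold. The group was chosen on ratios over the same control extracts, which can raise these values. On 922 probes chosen in replicate 2 alone, the median of PVC over control in replicate 1 was 0.40.

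The transcripts lower in PVC than in control were the higher ones here: daphmag3mtv3l16618t1, at 1.67 ± 0.13 (adjusted p = 0.342), and daphmag3mtv3l9809t1, at 1.16 ± 0.12 (adjusted p = 0.342). Against control, PVC+DINP stood at -0.50 ± 0.13 for daphmag3mtv3l16618t1 and at -0.23 ± 0.12 for daphmag3mtv3l9809t1. The lower transcripts were daphmag3mtv3l1209t1, at -1.04 ± 0.12, and daphmag3mtv3l21967t2, at -1.04 ± 0.17, both with an adjusted p of 0.342; daphmag3mtv3l1209t1 stood at -0.50 with slide row as a block. In limma no probe passed the threshold (lowest adjusted p 0.342), and 2186 probes had an unadjusted p under 0.05, 1869 of them higher; these included 248 of the 248 higher and 9 of the 53 lower in both replicates. Calls depended on which extract was left out, in fits where the spread of the lone extract left is not measured. The log2 ratio of daphmag3mtv3l16618t1 was 1.70 without PVC+DINP replicate 1 and 1.74 without PVC+DINP replicate 2. The 301 probes apart in the same direction in both replicates became 706 with the processed intensities.

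**Figure D2:**
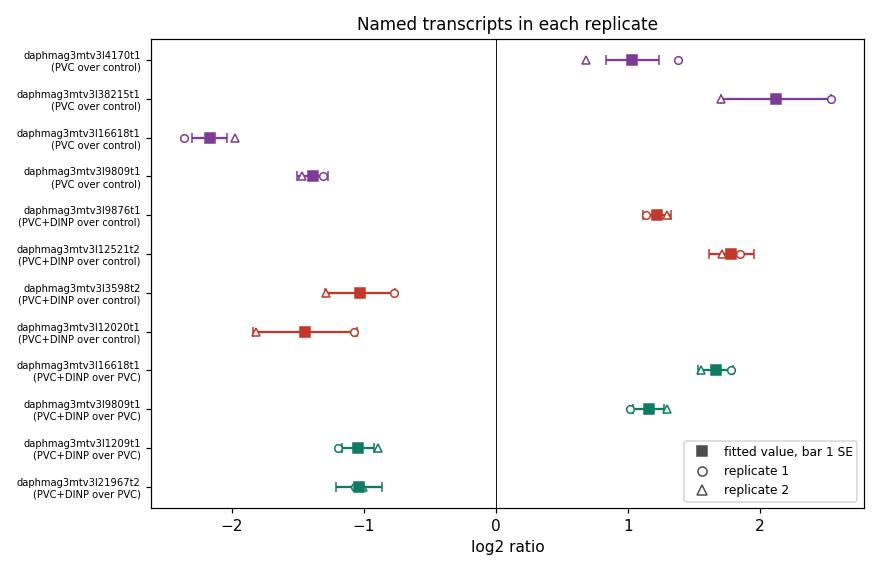
Log2 ratio of the named transcripts in each comparison; squares give the fitted value with a bar of 1 SE, circles replicate 1 and triangles replicate 2. Both replicates lie on the same side of 0 for every transcript, as the rule of choice required, and range from -2.37 to 2.54.

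Across probes, the log2 ratios of PVC over control and PVC+DINP over control correlated at 0.467, with a covariance of 0.0461. The correlation depended on single extracts, with 0.156 without PVC replicate 1 and 0.700 without control replicate 1. Unchanged conditions set against the same control extracts gave a mean correlation of 0.497 and a mean covariance of 0.0257 (0.0207 to 0.0998 over 50 data sets). The covariance exceeded the simulated mean by 0.0204 and lay within the simulated range, so a response shared by both exposures was not detected. Simulated noise was independent between probes, and the range reached far above its mean, so the simulations cannot exclude such a response. In the simulated data, shared control extracts alone gave a correlation of the size observed. Within a replicate, where both ratios hold the same control extract, the correlation was 0.694 in replicate 1 and 0.364 in replicate 2. Ratios that shared no control extract correlated at 0.00698 for PVC in replicate 1 with PVC+DINP in replicate 2, with a covariance of 0.00145, and at 0.0804 for PVC in replicate 2 with PVC+DINP in replicate 1, with a covariance of 0.0109. None of the 28 probes higher under PVC in both replicates was among the 527 higher under PVC+DINP. With 0.584 expected for independent lists, which these are not as they share control extracts, an overlap of 0 says little.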

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

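The Cy3 median signal of the array with PVC+DINP replicate 2 in Cy5 and control replicate 2 in Cy3 was 78.5, apart from the other 3 arrays of these conditions, which lay between 59 and 61. Its gap to the nearest of them was 0.897 of the whole range. This was the only sample far from the others among 8 sets of 4 arrays examined (4 array measures and 4 named transcripts), and chance gives about 1 in 20. The negative control spots of this array were also brighter in Cy3, with a median of 64.5 against 46 to 46.5 on the other 3. The only other array with control replicate 2 in Cy3, which carried PVC replicate 2 in Cy5, had the next highest Cy3 median signal, 67 against 58 to 61 on the remaining 6 arrays, and a Cy3 median of 54.5 on its negative control spots against 46 to 48. It also had the lowest share of probes well above background in Cy3, 39.3%. No explanation was tested. Both omissions that follow were chosen after the result was seen. Without the first array, 582 probes were at least 2-fold apart in the same direction in both replicates for PVC+DINP over control, and these included all 572 found with it; without both arrays, 584 were, including 571 of the 572.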

How the results depend on the processing

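Slide row, scale normalization, omission of the array of high green signal or both arrays with control replicate 2 in Cy3, and crossed numbers were chosen after seeing the data. Probes past the limma threshold stayed at 0 in every comparison and direction without background correction, with processed intensities, in the value table, under both other filters, without the dye effect, with an intensity trend, at an adjusted p under 0.10, with slide row or scale normalization and without that array or both. With no replicate block, separate-channel values gave 0 higher and 0 lower calls in each comparison. The main fit also gave 0 and used ratios as input, so this does not isolate the effect of pairing. Crossed PVC numbers gave 0 and 0 for PVC over control. Arrays as independent gave 13 higher and 45 lower calls for PVC over control, 2566 and 957 for PVC+DINP over control, and 1552 and 223 for PVC+DINP over PVC, counting repeated readings as replicates.

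Omitting 1 extract at a time, the lone extract left being assumed to vary like the others, gave 0 to 22 higher calls for PVC over control (22 without control replicate 2), 0 to 808 higher and 0 to 13 lower for PVC+DINP over control, and 0 to 740 higher and 0 to 36 lower for PVC+DINP over PVC. The maxima for PVC+DINP came without PVC+DINP replicate 1. PVC+DINP over control had 112 higher calls without PVC replicate 1, 54 without PVC replicate 2, and 9 lower without control replicate 1. The correlation of PVC with PVC+DINP responses ranged from 0.156 without PVC replicate 1 to 0.700 without control replicate 1, and was 0.332 with slide row.

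Probes at least 2-fold apart in the same direction in both replicates numbered, with processed intensities, 124 (103 higher, 21 lower) for PVC over control, 973 (884, 89) for PVC+DINP over control and 706 (544, 162) for PVC+DINP over PVC, including 34 of 34, 570 of 572 and 300 of 301 reported. The replicate correlation for PVC+DINP over control was then 0.407. The value table gave 58 (51 higher) for PVC over control and 80 lower for PVC+DINP over PVC. Requiring all 16 readings well above background, and so testing fewer probes, left 15 (9 higher) for PVC over control and 35 lower for PVC+DINP over PVC. Without the filter on dim probes the replicate correlation for PVC+DINP over PVC was 0.421. Without a dye effect, the replicate correlation was -0.377 for PVC over control and 0.103 for PVC+DINP over PVC, where dye orientation differs by replicate. Why these values moved was not tested. What is said of the stricter filter and the missing dye effect follows from how the tests and arrays were set up.

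The 12 named values kept their direction in all 252 recalculations; 84 left them as they were, and of the other 168, 4 moved one by over 1.5 times, 1 with slide row (-1.04 to -0.50) and 3 without a control extract (1.03 to 0.62, -1.03 to -0.65, -1.45 to -0.80). The threshold was passed in 16, 10 with arrays as independent and 6 without 1 extract, over adjusted p values from 0.000124 to 1.00. Aquantile leaves ratios unchanged. Slide as a block (1 slide) and gene-list tests were not run. Signal over background limits tests to 41.0% of probes.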

Other observations

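The tests of a shared control extract, of a fixed share and of shared ID stems were chosen after the results they measure had been seen. The 56 probes chosen for being higher in PVC in replicate 1 and lower in replicate 2 had median separate-channel levels (log2) of 7.27 in control replicate 1 and 10.49 in control replicate 2, 11.15 and 8.05 in the PVC extracts, and 8.34 and 6.81 in the PVC+DINP extracts. The 45 probes lower under PVC+DINP in both replicates stood at 9.66 and 11.11 in control, 10.48 and 7.16 in PVC, and 8.08 and 7.39 in PVC+DINP. Replicates 1 and 2 were never paired on an array, so these levels rest on normalization between arrays. In PVC replicate 2, 306 probes were at least 2-fold below control replicate 2, and 156 of them were also at least 2-fold lower in PVC+DINP replicate 2. Both ratios hold control replicate 2, so a high level in that extract would lower both.

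Transcripts whose IDs share a stem (the ID without its final t and number) had similar ratios of PVC+DINP over control: across 4321 stems with at least 2 tested transcripts, the first 2 correlated at 0.866, and shuffled pairs at -0.0050. Of 165 stems in the group of 527 higher probes that had a further tested transcript, 159 had all their transcripts above 0. In 77 of them all transcripts were at least 2-fold higher in both replicates. Both counts include the member that placed the stem in the group, and the share among other stems was not computed. Probes may be shared in sequence between such transcripts, which was not tested, so the value of 0.866 is consistent with transcripts of 1 gene changing together and with cross-hybridisation. Of the 22093 tested probes that are alone for their transcript, 523 were in the group of 527; of the 3181 remaining ones with several probes per transcript, 4 were.

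The excess of higher over lower probes under PVC+DINP was weighed against normalization and dye bias. The normalizations compared were no background correction, processed intensities, the value table and scale normalization. In each, higher probes made up at least 90.9% of the probes apart in the same direction. The excess therefore did not depend on the choice among these. All of them set ratios relative to the bulk of probes on the array, and scale normalization cannot change the sign of a ratio. They could not test a shift of the bulk itself. Probes chosen as higher in both replicates with PVC+DINP in Cy5 had a median log2 ratio of 2.02 on the arrays with PVC+DINP in Cy3, and those chosen in Cy3 had 1.90 in Cy5, which argues against dye bias and, as the orientations lay in different slide rows, against an effect of slide row. A response to PVC+DINP stays open as a hypothesis, as does a difference in stage or condition between the 2 PVC+DINP extracts and the controls, which was not tested.

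PVC replicate 1 lay part way between control and PVC+DINP. On 922 probes chosen in replicate 2 alone, with PVC+DINP at least 2-fold over control and PVC, the median of PVC over control in replicate 1 was 0.40, above all 10000 random lists matched on intensity. These lists address only noise that is independent between probes, so noise of the shared control extract stays open. On the same probes control replicate 1 lay 0.42 below control replicate 2 in separate channels, while PVC replicate 1 lay 0.058 above PVC replicate 2. A low control replicate 1 is therefore a candidate explanation. PVC+DINP was also lower in replicate 1, at -1.33 against replicate 2, in which the probes were chosen as high. PVC replicate 1 carrying a fixed share of PVC+DINP-like RNA may also account for the pattern. The linear share was taken on the 526 of these probes with PVC+DINP also at least 2-fold over control in replicate 1. It had a median of 28.0%, and the medians of 4 bins of the PVC+DINP response differed by at most 1.06 times. Control replicate 1 entered both this choice and the share. All 3 explanations stay open. No array joins the replicates, which limits the first 2, and an even share does not show where the RNA came from. Other readings, among them a response of PVC replicate 1 itself, were not tested.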
